A study of Mus musculus with 5 samples.

How the data were processed

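Gene expression was measured in 5 sorted mouse cell samples, 2 of brain dendritic cells and 3 of bone marrow monocytes, with 1 array per sample. Per the labels' protocols, total RNA was extracted with a Qiagen kit and biotinylated cRNA was prepared by the standard Affymetrix protocol. The deposited values were made with RMA, per the submitters' processing notes, and are taken to be on a log2 scale. RMA corrects background, normalises arrays by quantiles and summarises the probes of each probe set. The version of RMA, the centring and the set of arrays normalised together are not given in the sources used here. The log base is inferred: the range over the 5 arrays reached 8.86 in a probe set, a size that log2 values can take.

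The deposited values lie around 0 within each probe set. Array medians were between -0.05 and 0.00. In 970 probe sets, 2 of the 5 arrays held equal and opposite values within a tolerance of 1e-06, against 0 after values were shuffled between probe sets, which is what a median over an even number of arrays would leave. The baseline is therefore inferred to come from more arrays than the 5 used here. Differences between arrays within a probe set are kept, while levels between probe sets and detection above background are lost. Array processing dates were not used here, and no raw scans were analysed.

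The table held 45101 probe sets, of which 64 are controls. The platform annotation gave 1 gene symbol for 34945 probe sets, several for 932 and none for 9160. Symbols were checked against a reference gene table of assembly GRCm38.p6 by Entrez identifier: 34741 of the probe sets with 1 symbol had an entry, and 0 symbols needed an update. No genome build applies to the deposited values, so no coordinates are given. The 34945 probe sets cover 18194 genes, 9009 of them by more than 1 probe set.

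Before the data were examined, the groups, the tests, the gene lists, the alternatives and the rule for named genes were fixed. That plan took the probe set with the highest mean for each gene. Centred values have no meaningful mean level, so the average of a gene's probe sets, which the plan held as a second choice, was used instead, chosen before any test was run, and the written rule is reported as an alternative. Where a gene's probe sets disagreed, their range is given for some of the genes only. The planned filter on dim genes needs levels and was not run.

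Differences were tested with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes, no trend, no covariate), with Benjamini-Hochberg adjustment over the 18194 genes and a threshold of 0.05. The residual degrees of freedom were 3, the prior degrees of freedom 4.43 and the prior SD 0.165. The median difference over all genes was 0.09. The 39 gene lists named 534 different genes, of which 489 were measured, 35 were not named in the annotation used and 10 were only on probe sets with several symbols. Clec9a, among the first, and Ly6c1, among the second, could not be given a value of their own. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over all lists. Camera called 20 lists, 16 higher and 4 lower. With an estimated correlation 0 of the 20 were called, although all 20 kept their direction. That setting refers each statistic to the 3 residual degrees of freedom, so it has little power. The estimate lay below the preset for some called lists, such as -0.0282 for mature dendritic cells. It lay above the preset for others, such as 0.7256 for proliferation, 0.4609 for immediate early genes and 0.239 for MHC class I. For lists of the second kind, camera's p at the preset may be too small. With so little power, a call lost in that setting does not by itself show that correlated members made the shift. The fry test asks whether a list's genes move one way on balance and compares no list with other genes. Counts of called members are given over all genes and adjusted over the list alone, that is, with the adjustment made within the list.

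The named genes were the 10 with the largest increase and the 10 with the largest decrease among called genes without group overlap, up to 4 called members of each list with the largest difference, and a fixed set that included the sort gate genes and all Toll-like receptors. Members outside that rule that make up a count of 5 or fewer, such as Zeb2, Myb, Stat5b, Cebpd, Ctsl, Rfx5, Clec4a2, Cbr2, Ddx58 and Pcna, and the sex-linked genes were named after their values were seen.

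The scripts were tested on data simulated with the spread of the real comparison on 18194 genes, in 5 draws with 200 changed genes each. Of genes changed by 1 on the log2 scale 59.4% were called, and of those changed by 2, 98.0% were called. All called changed genes had the right sign, and 4.02% of calls were unchanged genes. The 200 changed genes are a far smaller share than the 33.8% called in the real comparison, and the adjustment depends on that share. Spreads were drawn from the prior that limma fitted, and no technical shift between the groups was simulated. These percentages therefore check the scripts and are not the power or false-call rate of the real comparison. In 1 further draw with no gene changed, limma called 0 genes. A shift of 1 was found in 20 of 20 simulated lists, and 1 of 698 unshifted lists was called. The simulated genes were drawn independently of each other, whereas estimated correlations in the real lists reached values such as 0.876 for primary granule genes. The simulation therefore does not give the rate of false list calls when members are correlated.

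The alternatives were the probe set rule, leaving out probe sets that can cross-hybridise, an intensity trend with robust variance, array weights, quantile normalisation of the 5 arrays, centring on array medians, a test against a 2-fold difference, the replicate number as a block, and leaving out each array. The median of a gene's probe sets and a test of each probe set on its own were added after the data were seen. Replicate correlations across genes, which are not independent replicates, were 0.826 between the brain DC arrays and 0.899 to 0.913 between monocyte arrays, and median absolute differences were 0.193 and 0.145 to 0.169. Figures were drawn with matplotlib version 3.10.9, and tables were made with Python version 3.11.15, numpy version 2.4.6 and pandas version 2.3.3.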

Results

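Gene expression was measured on Affymetrix arrays in 2 cell populations sorted from C57BL/6 mice, with 1 array per sample. The brain dendritic cell (DC) group held 2 arrays of lineage-negative, CD45-high, CD11c-positive cells from mice inoculated under the skin with B16-Flt3L tumour cells 12 days before harvest. B16 is a mouse melanoma line, and Flt3 ligand is a growth factor for dendritic cells. The bone marrow monocyte group held 3 arrays of cells with low side scatter, high CD11b and surface CD115, and the labels give no treatment for it. All 5 samples are labelled female, 6 to 8 weeks old. The series also names microglia and spleen dendritic cells, which were not analysed here. The labels do not say that the samples came from separate animals, so p-values measure only the spread between these samples, which may be technical. The values are log2 values relative to a baseline of each probe set, so they give differences between arrays and no absolute level. The number of arrays limits the precision: an exact two-sided permutation test of 2 against 3 arrays cannot give a p below 0.1, so calls rest on the limma model fitted across all genes. Differences below are log2, brain DC minus monocyte, with the SE of the limma fit (n = 2 brain DC and 3 monocyte arrays), and gene calls use an adjusted p threshold of 0.05.

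The first question was which genes separated brain DCs from bone marrow monocytes. Of 18194 genes, 3067 were higher in brain DCs, 3083 were lower and 12044 were not called, and 1097 of the higher and 1367 of the lower genes differed at least 2-fold. The largest increase was in P2ry10, a G protein-coupled receptor of lymphoid and dendritic cells, which was 250-fold higher (7.97 ± 0.28 SE, limma adjusted p = 3.09e-06). Cd83, a surface protein of mature dendritic cells, was 233-fold higher (7.86 ± 0.23, limma adjusted p = 1.75e-06). Ttr, which encodes the thyroxine carrier transthyretin made by the choroid plexus and liver, was 150-fold higher (7.22 ± 0.12, limma adjusted p = 5.73e-07), with its 4 probe sets between 3.43 and 8.76. The other genes among the 10 largest increases were Gm6377 (7.86), Hepacam2 (7.38), Ctla2b (6.89), the natural killer cell receptor gene Klrd1 (6.29), Gpr171 (6.26), the complement gene C1qb (6.23) and the G protein regulator Rgs1 (6.16). Fn1, which encodes fibronectin, had the largest decrease, 61.2-fold (-5.94 ± 0.20, limma adjusted p = 2.92e-06). It was followed by Cd177, a neutrophil surface antigen, 50.9-fold lower (-5.67 ± 0.15), and F13a1, the A subunit of coagulation factor XIII, 41.1-fold lower (-5.36 ± 0.12). The other large decreases were the neutrophil collagenase gene Mmp8 (-4.75), the myeloperoxidase gene Mpo (-4.64), Dmxl2 (-4.59), the coagulation factor V gene F5 (-4.58), the glycogen phosphorylase gene Pygl (-4.55), the proteinase 3 gene Prtn3 (-4.53) and Cd300lb (-4.45). All 6150 called genes had groups that did not overlap, as did 10943 of all genes, where chance gives 20%. Cell type, tissue, treatment and the sex-linked transcripts given below all separated the groups in the same way, so their effects cannot be told apart in any comparison here. Array processing dates were not used, so a processing round that differed between the groups cannot be told apart either. The 24 probe sets of poly-A spike-ins, RNA added during labelling that no mouse cell makes, were all higher in the brain DC arrays, by a median of 2.59.

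**Figure D1:**
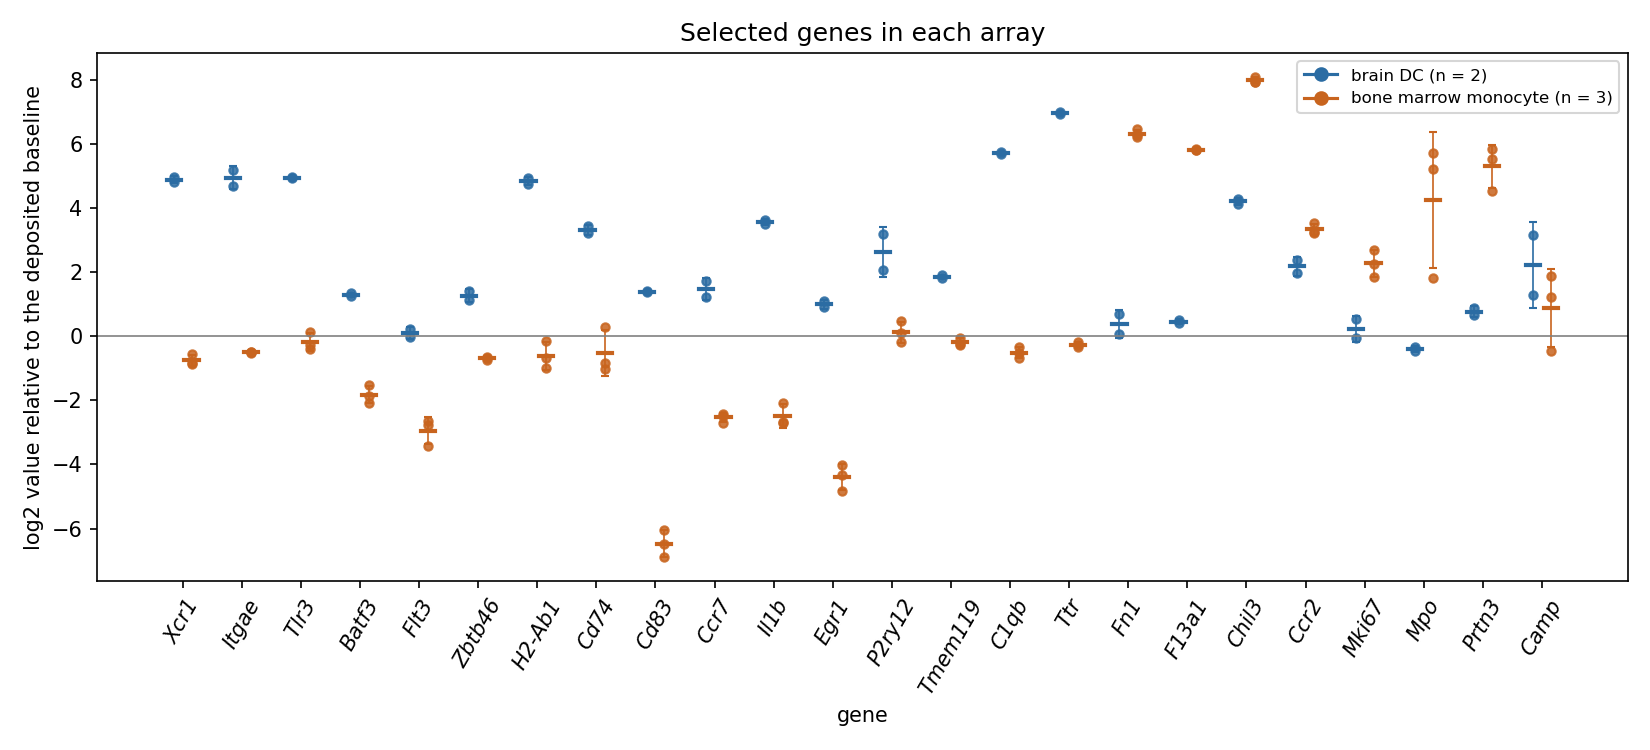
Log2 values of 24 genes relative to the deposited baseline (vertical axis) in each of the 2 brain DC arrays and 3 bone marrow monocyte arrays, with horizontal lines at group means and bars of 1 SD. Mpo spreads widely among monocytes (SD 2.13), and Camp overlaps between the groups.

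The genes of the sort gates were checked against the labels and are not findings. Itgax, which encodes CD11c, was 32.4-fold higher in brain DCs (5.02 ± 0.21, limma adjusted p = 5.89e-06). Itgam, which encodes CD11b, was 4.87-fold lower (-2.28 ± 0.42), and Csf1r, which encodes CD115, was 2.65-fold lower (-1.40 ± 0.18). Ptprc, which encodes CD45, was lower by a smaller amount (-0.63 ± 0.14, limma adjusted p = 0.0124), and its call was lost without brain DC replicate 2 (-0.55, limma adjusted p = 0.0593).

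Most genes of the conventional dendritic cell core, type 1 and mature lists were higher in brain DCs, while type 2 genes went both ways. Of 24 measured genes of the conventional dendritic cell core, 21 were higher, 0 lower and 3 not called, or 22 higher when adjusted over the list alone. Flt3, the receptor of Flt3 ligand, was 8.32-fold higher (3.06 ± 0.24), Traf1, a TNF receptor adaptor, 23.8-fold (4.57 ± 0.14), and Slamf7 14.7-fold (3.88 ± 0.33). Zbtb46, a transcription factor of conventional dendritic cells, was 3.86-fold higher (1.95 ± 0.14), although its 4 probe sets ranged from 0.31 to 4.10. The list was called by camera (adjusted p = 1.89e-12) but not when the correlation was estimated (adjusted p = 0.154 with an estimated correlation). All 12 measured genes of type 1 conventional dendritic cells, the cross-presenting subset, were higher, both over all genes and adjusted over the list alone, with a median of 3.08. Among them Xcr1, the receptor of the chemokine XCL1, was 49.9-fold higher (5.64 ± 0.15), the integrin gene Itgae, which encodes CD103, 43.5-fold (5.44 ± 0.17), and the adhesion gene Cadm1 30.0-fold (4.91 ± 0.12), although its 4 probe sets ranged from 1.02 to 7.15. The camera adjusted p of this list was 6.55e-11, against an adjusted p = 0.154 with an estimated correlation. The 8 measured genes of type 2 conventional dendritic cells went both ways, with 4 higher, 2 lower and 2 not called, and the same counts adjusted over the list alone (camera adjusted p = 0.186). The lectin genes Cd209a (4.06 ± 0.20) and Mgl2 (4.06 ± 0.28) were higher, whereas Sirpa, an inhibitory receptor (-1.35 ± 0.14), and Clec4a2 (-1.15) were lower and Irf4 was at 0.18 and not called. Of 14 measured genes of mature dendritic cells, 10 were higher, 0 lower and 4 not called, or 11 higher adjusted over the list alone. They included Ccr7, the receptor that guides dendritic cells to lymph nodes (1.47 ± 0.35 SD in brain DCs against -2.53 ± 0.14 SD in monocytes), and the chemokine genes Ccl22 (3.52 ± 0.23) and Ccl17 (3.32 ± 0.15). Camera called this list (adjusted p = 2.02e-06), with adjusted p = 0.165 with an estimated correlation. Among 12 measured genes of plasmacytoid dendritic cells, 6 were higher, 0 lower and 6 not called, or 8 higher adjusted over the list alone, with Bst2 (3.10 ± 0.16), Spib (2.59 ± 0.17) and Siglech (1.78 ± 0.13) higher and Tcf4 at -0.13 and not called. That list had a camera adjusted p of 0.00148 and an adjusted p = 0.240 with an estimated correlation.

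The study set out to compare molecules of antigen processing and presentation, and most MHC class II genes were higher in brain DCs. Of 20 measured genes of the class II pathway, 12 were higher, 2 lower and 6 not called, or 12 higher and 3 lower adjusted over the list alone. H2-Ob (5.74 ± 0.22) and H2-Oa (5.27 ± 0.20), which encode the DO modulator of peptide loading, H2-Ab1, a class II beta chain (5.45 ± 0.24), and Cd74, the invariant chain (3.85 ± 0.36), were all higher. Ciita, the class II transactivator, was 3.14-fold higher (1.65 ± 0.19), with probe sets from 0.14 to 2.59. The lower genes were the protease gene Ctsl (-0.68) and the class II promoter factor gene Rfx5 (-0.93), and without brain DC replicate 1, monocyte replicate 1 or monocyte replicate 2 only 1 gene was lower. The list was called by camera (adjusted p = 4.35e-04) and lost its call when the correlation was estimated (adjusted p = 0.240 with an estimated correlation). In MHC class I processing, 14 of 18 measured genes were higher, 0 lower and 4 not called, or 15 higher adjusted over the list alone. The immunoproteasome genes Psmb9 (2.59 ± 0.13) and Psmb8 (2.16 ± 0.14), the proteasome activator gene Psme1 (2.37 ± 0.17) and the peptide transporter gene Tap2 (1.52 ± 0.18) were higher, and Canx, a chaperone, was at -0.05. The camera adjusted p was 7.52e-06, with adjusted p = 0.258 with an estimated correlation. The count of 14 fell to 9 without brain DC replicate 2 or without monocyte replicate 3, and to 7 when each gene was read from its probe set with the highest mean.

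Endocytic and pattern-recognition receptors moved in both directions. Of 28 measured lectin and scavenger receptors, 12 were higher, 7 lower and 9 not called, with the same counts adjusted over the list alone, a median of 0.14 and no call by camera (adjusted p = 0.433). Cd36, a scavenger receptor for lipids, was 39.8-fold higher (5.31 ± 0.18), whereas Lrp1, a receptor that clears lipoproteins and protease complexes, was 11.8-fold lower (-3.56 ± 0.20). The mannose receptor gene Mrc1 was at 0.05 and not called. Of 15 measured Fc and complement receptors, 5 were higher, 3 lower and 7 not called, or 7 higher and 3 lower adjusted over the list alone (camera adjusted p = 0.293). The IgG receptor gene Fcgr4 (3.43 ± 0.28) and the neonatal Fc receptor gene Fcgrt (2.47 ± 0.17) were higher, and Fcgr1 was at -0.23 and not called. Both gate integrins, Itgax and Itgam, belong to this list.

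Cytokine receptors as a list did not stand apart from other genes. Among 37 measured, 10 were higher, 8 lower and 19 not called, or 11 higher and 8 lower adjusted over the list alone (camera adjusted p = 0.911). The median was 0.02 and the mean 0.19, while camera pointed down and fry up. The decoy interleukin 1 receptor gene Il1r2 was 45.2-fold higher (5.50 ± 0.13), Kit, the stem cell factor receptor, 4.16-fold higher (2.06 ± 0.19), and the G-CSF receptor gene Csf3r 4.31-fold lower (-2.11 ± 0.17). The gate gene Csf1r is among the 8 lower ones. The 10 higher receptors became 6 without brain DC replicate 2 or without monocyte replicate 2. Of 14 measured chemokine receptors, 7 were higher, 2 lower and 5 not called, with the same counts adjusted over the list alone. Xcr1, Ccr7, the atypical receptor gene Ccrl2 (4.98 ± 0.28) and Cxcr3 (3.73 ± 0.28) were higher. Cx3cr1, the fractalkine receptor (-2.56 ± 0.22), and Ccr2, the receptor that takes monocytes out of the marrow (-1.15 ± 0.17), were the 2 lower ones. Camera called this list (adjusted p = 0.0136), with adjusted p = 0.495 with an estimated correlation.

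Toll-like receptors split by member. Of 11 measured, 3 were higher, 5 lower and 3 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.215). Tlr3, the receptor of double-stranded RNA, was 34.9-fold higher (5.12 ± 0.18, limma adjusted p = 2.92e-06), Tlr12 was higher by 1.01 ± 0.15 and Tlr9, a receptor of DNA, by 0.45 ± 0.13. Lower were Tlr1 (-1.16), Tlr13 (-1.15), the lipopolysaccharide receptor gene Tlr4 (-0.98), Tlr6 (-0.92) and the flagellin receptor gene Tlr5 (-0.65). Tlr7 at -0.50, Tlr2 at -0.16 and Tlr8 at -0.12 were not called. The median was -0.50 and camera pointed down, but the mean was 0.09 and fry pointed up, with Tlr3 the largest member. Tlr9 lost its call without any 1 of the 5 arrays (limma adjusted p from 0.0599 to 0.105), Tlr5 without brain DC replicate 1 (limma adjusted p = 0.0561), and Tlr12 when read from its probe set with the highest mean (0.36, limma adjusted p = 0.108). With that probe set rule, 1 receptor was higher instead of 3. Of 13 measured cofactors and signalling genes, 3 were higher, 2 lower and 8 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.920). The lipopolysaccharide co-receptor gene Cd14 was higher (2.31 ± 0.36), and the inhibitory kinase gene Irak3 (-2.56 ± 0.21) and the adaptor gene Tirap (-1.57 ± 0.13) were lower. The median of this list was 0.26, while its mean was -0.01 and camera and fry pointed down. Without monocyte replicate 2, 4 of these genes were lower instead of 2.

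Of 38 measured transcription factors of myeloid and dendritic cells, 17 were higher, 4 lower and 17 not called, or 17 higher and 5 lower adjusted over the list alone. The immediate early factor gene Egr1 was 42.0-fold higher (5.39 ± 0.23), Batf3, which type 1 conventional dendritic cells require, 8.65-fold (3.11 ± 0.18), Nr4a1 8.52-fold (3.09 ± 0.19), and the NF-kappaB gene Rel 7.08-fold (2.82 ± 0.18). The lower factors were Zeb2 (-2.65), Myb (-2.22), Stat5b (-1.19) and Cebpd (-0.79), and Cebpb was at -0.14 and not called. The list was not called by camera (adjusted p = 0.0616, and adjusted p = 0.276 with an estimated correlation), but passed the threshold without brain DC replicate 1 (adjusted p = 0.0174) and without monocyte replicate 3 (adjusted p = 0.0379). When genes were read from the probe set with the highest mean, 8 factors were lower instead of 4.

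Most measured costimulatory molecules, cytokines and early response genes were higher in brain DCs. Of 14 measured costimulatory and coinhibitory molecules, 12 were higher, 0 lower and 2 not called, with the same counts adjusted over the list alone. Tnfsf9, the 4-1BB ligand, was 20.1-fold higher (4.33 ± 0.23) and Cd86, a CD28 ligand, 7.18-fold (2.84 ± 0.16), while Cd40 was at 0.42 and not called. The camera adjusted p was 1.73e-06, with adjusted p = 0.166 with an estimated correlation. Of 30 measured cytokines and chemokines, 21 were higher, 0 lower and 9 not called, or 21 higher and 1 lower adjusted over the list alone. Read from the probe set with the highest mean, 22 were higher and 2 lower, and with the replicate block 20 and 1. Il1b, the inflammatory cytokine interleukin 1 beta, was 66.5-fold higher (6.06 ± 0.21), Cxcl16 30.0-fold (4.91 ± 0.14), the neutrophil attractant gene Cxcl2 27.7-fold (4.79 ± 0.91), and Ccl4 17.9-fold (4.16 ± 0.12). That list had a camera adjusted p of 1.37e-09 and an adjusted p = 0.208 with an estimated correlation. Immediate early and heat shock genes, which respond to stress and to tissue handling among other stimuli, moved with these groups: 17 of 18 measured were higher, 0 lower and 1 not called, or 17 higher and 1 lower adjusted over the list alone. Besides Egr1 they included Fosb (5.06 ± 0.29), Egr3 (4.12 ± 0.12, with probe sets of 0.86 and 7.38) and Egr2 (3.99 ± 0.20), and Fos was at -0.38 and not called. The median was 2.83, with a camera adjusted p of 7.38e-11 and an adjusted p = 0.242 with an estimated correlation.

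Interferon response genes showed a mixed picture. Of 21 measured type I interferon response genes, 8 were higher, 1 lower and 12 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.163, and adjusted p = 0.772 with an estimated correlation). Ifi27l2a (1.80 ± 0.30), the interferon regulatory factor gene Irf7 (1.57 ± 0.27) and Ifit3 (1.35 ± 0.26) were higher, while Mx1 was at 0.16 and not called. The 8 higher genes became 4 without brain DC replicate 2, and the lower gene, the RNA sensor Ddx58 (-0.75), lost its call without brain DC replicate 1 or monocyte replicates 1 or 3. With camera the list passed the threshold with quantile normalisation (adjusted p = 0.0376), without brain DC replicate 1 (adjusted p = 0.0298) and without monocyte replicate 1 (adjusted p = 0.0134). Of 10 measured interferon gamma response genes, 3 were higher, 1 lower and 6 not called, or 5 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.558). The chemokine gene Cxcl9 (1.73 ± 0.20) and the GTPase gene Iigp1 (1.26 ± 0.17) were higher and the guanylate-binding protein gene Gbp3 was lower (-2.36 ± 0.20), and without monocyte replicate 2 the lower genes became 2.

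Most measured classical monocyte, primary granule and proliferation genes were lower in brain DCs. Of 14 measured classical monocyte genes, 9 were lower, 1 higher and 4 not called, with the same counts adjusted over the list alone and a median of -1.57. Besides Fn1 and F13a1, F10, coagulation factor X (-4.08 ± 0.21), and Chil3, a chitinase-like protein (-3.78 ± 0.13), were lower, and Cd14 was the gene that was higher. The camera adjusted p was 2.48e-07, with adjusted p = 0.240 with an estimated correlation. Of 9 measured genes of primary granules and granulocyte-monocyte progenitors, 6 were lower, 1 higher and 2 not called, with the same counts adjusted over the list alone. Prtn3 (-4.53 ± 0.34), Ctsg (-3.57 ± 0.48) and Elane (-2.38 ± 0.42), all serine proteases of primary granules, were lower, and the progenitor marker Cd34 was higher (2.91 ± 0.42). Mpo was at 1.81 in monocyte replicate 1 and at 5.72 and 5.22 in replicates 2 and 3 (limma adjusted p = 0.0108), and lost its call without brain DC replicate 1 (limma adjusted p = 0.0512) or 2 (limma adjusted p = 0.0523). That list had a camera adjusted p of 0.00859, an adjusted p = 0.519 with an estimated correlation and no call by fry (adjusted p = 0.0973). Of 24 measured proliferation genes, 17 were lower, 1 higher and 6 not called, or 19 lower and 1 higher adjusted over the list alone. Kif11, a mitotic motor (-2.38 ± 0.32), Rrm2, a subunit of ribonucleotide reductase (-2.37 ± 0.39), and Mki67 (-2.04 ± 0.27) were lower, whereas Pcna was higher (0.91). Camera called this list (adjusted p = 3.57e-07), with adjusted p = 0.482 with an estimated correlation and no call by fry (adjusted p = 0.0593). Without brain DC replicate 1, 10 of these genes were lower and 0 higher.

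Of 6 measured NADPH oxidase and lysozyme genes, 0 were higher, 4 lower and 2 not called, or 1 higher and 5 lower adjusted over the list alone (camera adjusted p = 0.0132, and adjusted p = 0.414 with an estimated correlation). Cybb, the catalytic subunit of the phagocyte oxidase (-1.99 ± 0.13), and Lyz2, lysozyme (-1.05 ± 0.12), were lower, and without brain DC replicate 1 the 4 lower genes became 2. Of 13 measured neutrophil genes, 2 were higher, 4 lower and 7 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.305). Cd177 and Mmp8 were lower, S100a9 was higher (1.41 ± 0.28), and the granule peptide gene Camp was at 1.33 and not called (limma adjusted p = 0.205). The median of this list was 0.25, while its mean was -0.61 and camera and fry pointed down, and 1 gene was higher without brain DC replicate 2, monocyte replicate 1 or monocyte replicate 3. Of 10 measured nonclassical monocyte genes, 4 were higher, 1 lower and 5 not called, or 7 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.0804, and adjusted p = 0.495 with an estimated correlation). With camera this list passed the threshold without brain DC replicate 1 (adjusted p = 0.0477) and without monocyte replicate 1 (adjusted p = 0.0463), and the lower genes became 2 without brain DC replicate 2. Its members included Cd36 and Nr4a1, both higher, and Cx3cr1, which was lower. Of 13 measured integrins and adhesion molecules, 4 were higher, 2 lower and 7 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.346), and 1 was lower without brain DC replicate 1 or monocyte replicate 1. Icam1, a ligand of leukocyte integrins, was higher (1.94 ± 0.15), and Itgal was at -0.32 and not called. The counts of this list include the gate genes Itgax, which was higher, and Itgam, which was lower.

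**Figure D2:**
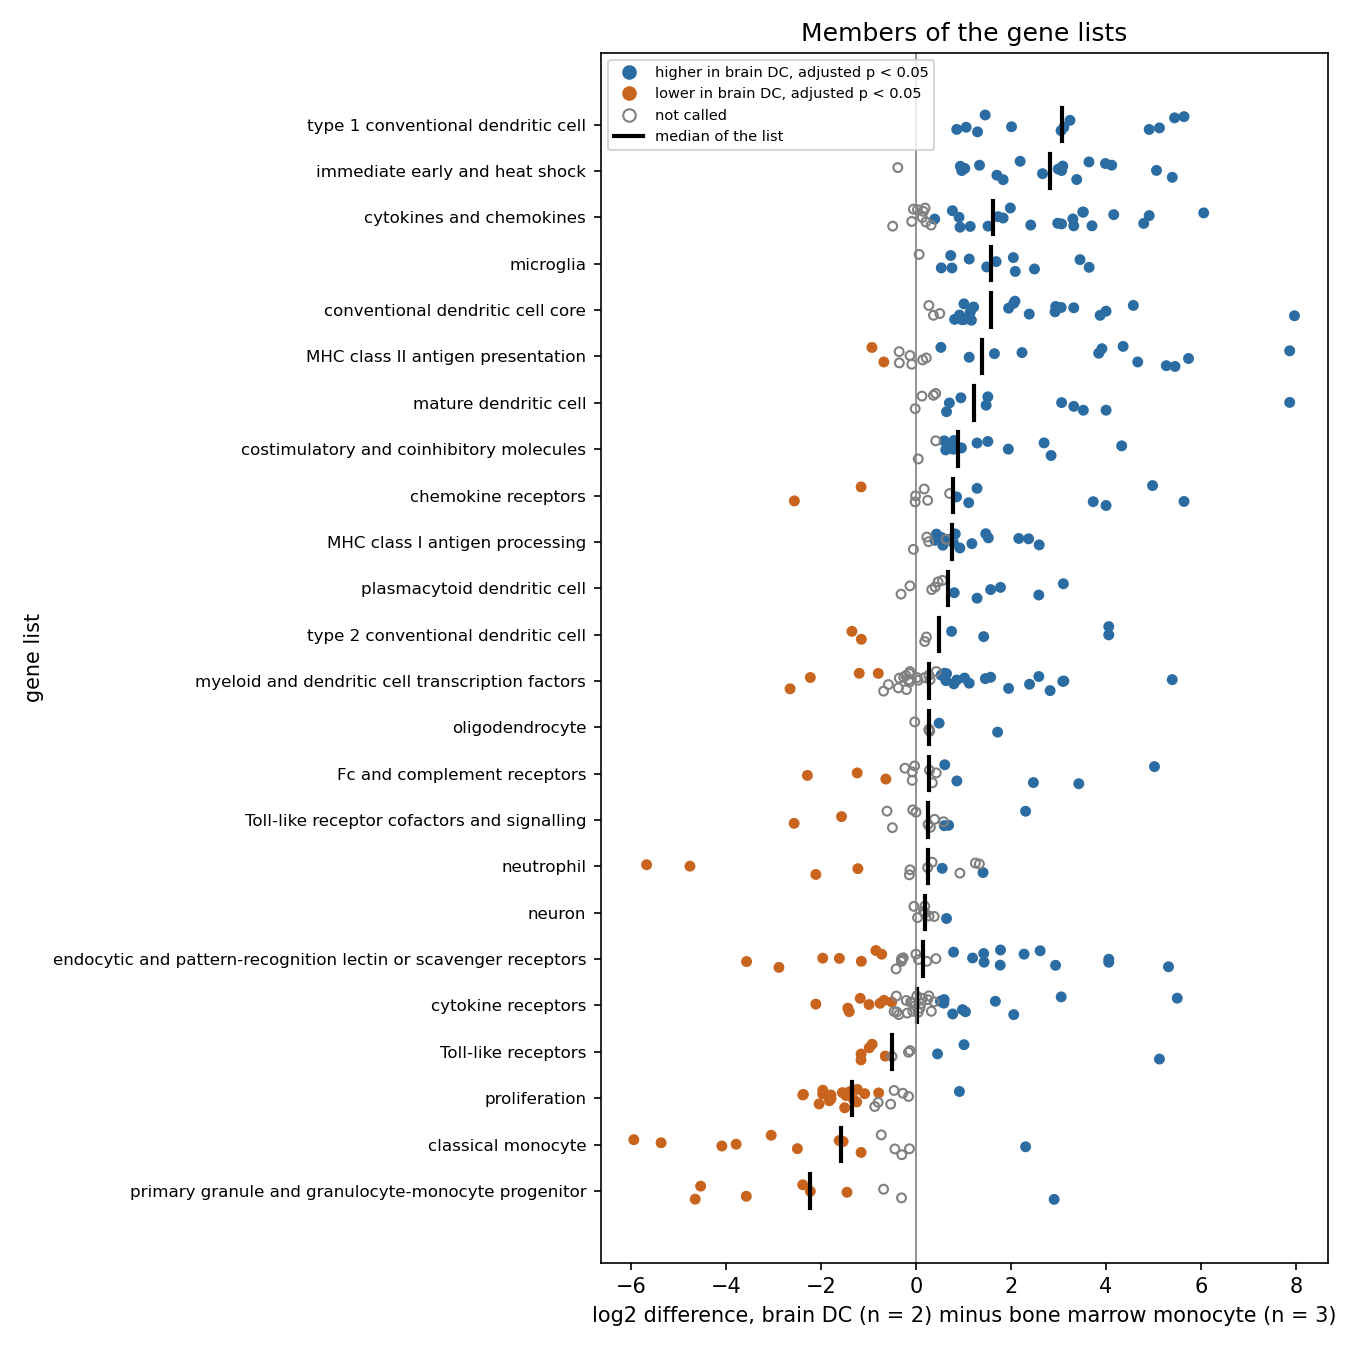
Log2 difference of every measured member of 24 gene lists (horizontal axis, brain DC minus bone marrow monocyte), with lists ordered by their median (black line). All 12 type 1 conventional dendritic cell genes lie above 0, and the classical monocyte list has a median of -1.57.

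Microglia and border-associated macrophage lists were also called higher in the brain DC arrays. Of 12 measured microglia genes, 11 were higher, 0 lower and 1 not called, with the same counts adjusted over the list alone and a median of 1.59. The orphan receptor gene Gpr34 (3.64 ± 0.21), Fcrls (3.45 ± 0.15), the purine receptor gene P2ry12 (2.49 ± 0.33) and Tmem119 (2.05 ± 0.13) were higher, and Trem2, a lipid receptor of microglia and macrophages, was at 0.07 and not called. Camera called the list (adjusted p = 2.02e-06), with adjusted p = 0.166 with an estimated correlation. Of 12 measured genes of border-associated macrophages, 7 were higher, 1 lower and 4 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.00265, and adjusted p = 0.240 with an estimated correlation). The complement genes C1qb (6.23 ± 0.14), C1qc (4.62 ± 0.15) and C1qa (4.46 ± 0.18) were higher, and the lower gene was Cbr2 (-1.18). Of 10 measured genes of lipid-associated microglia, 2 were higher, 2 lower and 6 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.942). The higher genes were the gate gene Itgax and Csf1 (0.39), and the lipase gene Lpl was lower (-2.94 ± 0.33). Without any 1 of the 3 monocyte replicates, 1 gene of that list was higher. Csf1 lost its call in each of these fits (limma adjusted p from 0.0884 to 0.103) and with quantile normalisation (limma adjusted p = 0.0514).

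Astrocyte, endothelial and choroid plexus lists were called higher by camera, while neuron and oligodendrocyte lists were not. Of 8 measured astrocyte genes, 4 were higher and 4 not called, including Aldoc (2.61 ± 0.23) and Clu (1.77 ± 0.15), with Gfap at 0.13 (camera adjusted p = 0.00859, and adjusted p = 0.240 with an estimated correlation). Of 9 measured endothelial and pericyte genes, 6 were higher and 3 not called, including the tight junction gene Cldn5 (2.56 ± 0.24) (camera adjusted p = 0.0118, and adjusted p = 0.240 with an estimated correlation). Among 3 measured choroid plexus genes, Ttr was higher and 2 were not called, or 2 higher adjusted over the list alone (camera adjusted p = 0.0318, and adjusted p = 0.243 with an estimated correlation). Of 8 measured neuron genes, 1, Nrgn (0.64), was higher, a call lost without brain DC replicate 1 (0.56, limma adjusted p = 0.0777), and 7 were not called (camera adjusted p = 0.346), with the synaptic gene Snap25 at 0.27. Of 6 measured oligodendrocyte genes, 2 were higher and 4 not called (camera adjusted p = 0.125), with Cnp higher (1.72 ± 0.12) and Mbp at 0.29, with its 8 probe sets between -1.47 and 1.58, and 1 was higher without brain DC replicate 1 or any 1 of the 3 monocyte replicates. Counts adjusted over the list alone were the same for the astrocyte, endothelial, neuron and oligodendrocyte lists. Without any 1 of the 3 monocyte replicates, the 6 higher endothelial genes became 4.

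Of 12 measured T and natural killer cell genes, 5 were higher and 7 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.0227, and adjusted p = 0.240 with an estimated correlation). Klrd1 was 78.1-fold higher (6.29 ± 0.30) and the granzyme gene Gzma 6.73-fold (2.75 ± 0.31), while Cd3e, a subunit of the T cell receptor complex, was at 0.19 and not called. The higher genes also included Gzmb (1.56) and Cd5 (0.97), and Cd5 lost its call without brain DC replicate 1 (0.78). Without any 1 of the 3 monocyte replicates, 4 of these genes were higher, and without monocyte replicate 1 there was also 1 lower. Of 10 measured B cell genes, 2 were higher and 8 not called, with the same counts adjusted over the list alone (camera adjusted p = 0.210). They were Fcrla (3.47 ± 0.24) and Ms4a1 (1.00 ± 0.16), with Cd79a at -0.14, and 3 were higher and 1 lower without brain DC replicate 2. Of 6 measured erythroid genes, 1 was higher, Alas2 (0.79), a call lost without brain DC replicate 1 or any 1 of the 3 monocyte replicates, and 0 when adjusted over the list alone (camera adjusted p = 0.496). None of the 5 melanocyte genes was called by limma over all genes or adjusted over the list alone (camera adjusted p = 0.974), and Tyr was at 0.14 and Mlana at -0.33. Of 6 measured reference genes, 1 was higher, with the same count adjusted over the list alone (camera adjusted p = 0.484). That gene was Actb (1.01 ± 0.22), whose 2 probe sets differed by -0.34 and 2.36. Actb lost its call without brain DC replicate 1 (0.86, limma adjusted p = 0.0695), and read from the probe set with the highest mean it was at -0.34 (limma adjusted p = 0.130).

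Control probe sets and sex-linked transcripts separated the same groups as the genes above. The poly-A spike-ins differed by between 1.31 and 3.52, and the 18 probe sets of hybridisation spike-ins, added before the array step, were all higher in brain DC arrays, by a median of 1.04. For Actb, the 5′ minus 3′ gap of the control probe sets was 0.24 ± 0.11 (SD, n = 2) in brain DC arrays and -3.19 ± 1.38 (SD, n = 3) in monocyte arrays. For Gapdh it was 0.28 ± 0.08 (SD, n = 2) and -2.64 ± 0.32 (SD, n = 3). Each probe set has its own baseline, so a gap within an array is no 5′ to 3′ ratio. Only the difference in gap between the groups can be read. Xist, the RNA that silences an X chromosome in female cells, averaged 0.23 ± 0.15 (SD, n = 2) in brain DC arrays and -8.26 ± 0.32 (SD, n = 3) in monocyte arrays on the first of its 3 probe sets, and all 3 were lower in monocytes without overlap. The Y-linked gene Eif2s3y was at 6.57 and 5.83 in the brain DC arrays and at 7.10, 7.23 and 6.92 in the monocyte arrays on its more variable probe set. On 1 of its 3 probe sets Kdm5d, also Y-linked, averaged 0.88 ± 0.84 (SD, n = 2) against 4.17 ± 0.14 (SD, n = 3), while on the others, with differences of -0.28 and 0.30, the groups overlapped. All samples carry a female label.

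**Figure D3:**
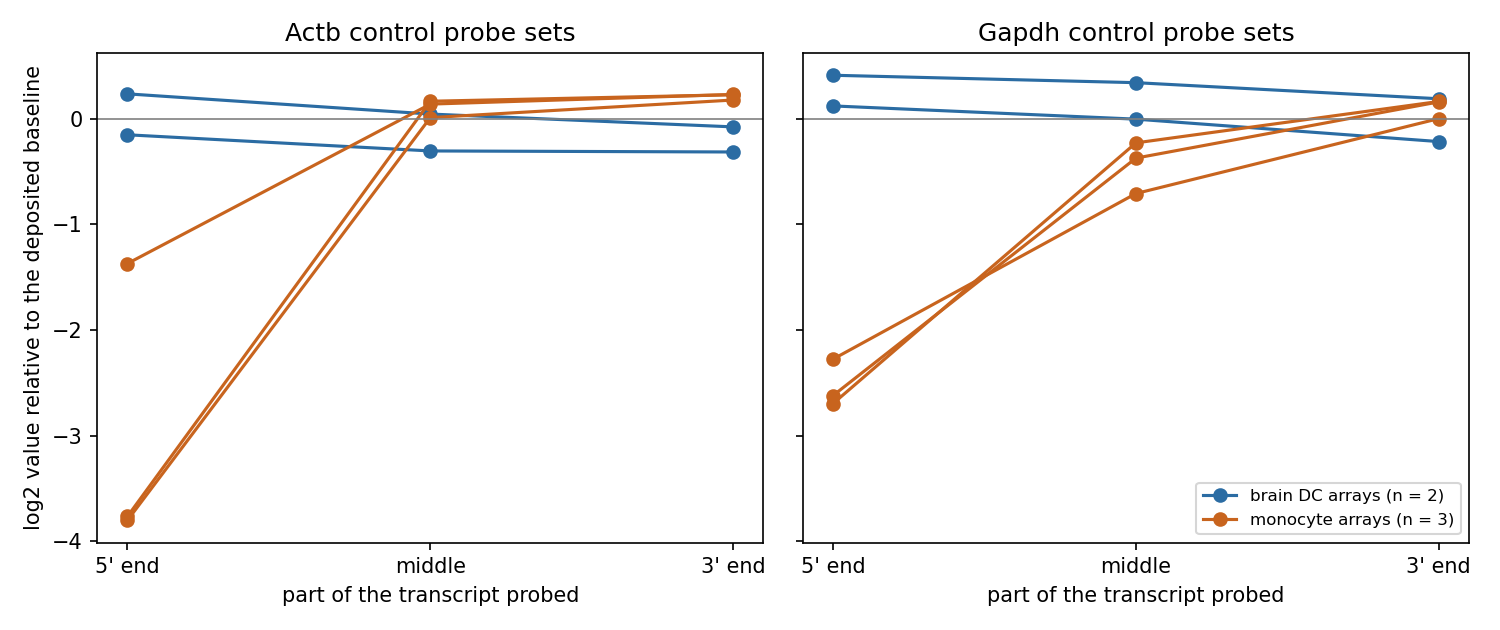
Log2 values relative to the deposited baseline (vertical axis) of control probe sets at the 5′ end, middle and 3′ end of Actb and Gapdh transcripts (horizontal axis), with 1 line per array. Relative to their baselines, the 5′ probe sets lie below the 3′ ones in the 3 monocyte arrays, with mean gaps of -3.19 for Actb and -2.64 for Gapdh. Each probe set has its own baseline, so only the difference between the groups in this gap can be read.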

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

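All tests in this part were chosen after the results were seen. Signals in probe sets that the gene comparison does not use brought these results up. The poly-A spike-in probe sets had a median difference of 2.587 and the hybridisation spike-ins one of 1.042, with 24 of 24 and 18 of 18 probe sets higher in brain DC arrays without overlap. The hybridisation spike-ins ranged from 0.1654 to 1.3624. The TrpnX control probe sets, in neither set, were at -0.0693, 0.2907 and -0.1155. The difference between groups in the 5′ minus 3′ gap was 3.427 for Actb and 2.918 for Gapdh, but 0.209 for pyruvate carboxylase, and for the transferrin receptor the groups overlapped at 0.101. Among 10092 probe sets with several or no symbols, 448 were at least 2-fold higher in brain DCs without overlap, and 906 at least 2-fold lower. Chance gives 20% of probe sets without overlap at any size. That share was not counted for these probe sets, so the counts cannot be set against it.

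The genes called higher in brain DCs stand beside these control signals. Loss of 5′ signal in the monocyte arrays stays open. In 86.56% of called higher genes with several probe sets (1211 of 1399) every probe set was higher, but the genes were called on the average of those probe sets, and position along the transcript was not used. A labelling or hybridisation round that differed between the groups stays open: the spike-ins differed by a median of 2.587, as such a round would give, and it cannot be told apart from the cell types because each group would lie in a round of its own. The cell type, tissue and tumour treatment that the labels name are open too and were not tested separately.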

How the results depend on the processing

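The median of a gene's probe sets and the test of each probe set were chosen after the data were seen; the other alternatives were planned. Counts of genes higher in brain DCs and genes lower in brain DCs stayed within 1.5 times of 3067 and 3083 under all alternatives but 2. A test against a 2-fold difference, which asks for more, gave 432 higher and 367 lower, and each probe set tested on its own, over 34945 units, gave 4704 higher and 5865 lower, with 2322 and 3712 of at least 2-fold. Leaving out 1 array gave 2236 to 2447 higher and 2371 to 2806 lower, and where 1 brain DC array was left, it was assumed to vary like the monocytes. The highest-mean rule gave 2595 and 3133, and quantile normalisation 3057 and 2995. Similar counts do not mean the same genes. Of the 3067 higher and 3083 lower genes, 2257 and 2596 kept their call with the highest-mean rule. Without monocyte replicate 3, 2187 and 2577 did. The median difference of all genes stayed between 0.05 and 0.10. The replicate block gave 2513 and 3005. Only monocyte replicate 3 holds its number, so the block fits that array away. Its differences equalled those without monocyte replicate 3, such as 0.4872 for Tlr9, so it is no separate check of them. Deviations across genes correlated at 0.045 and 0.088 between arrays sharing a number. With 2 brain DC arrays their deviations are opposite, so mismatched pairs mirrored these values, at -0.045 and -0.088. The correlations therefore cannot show whether the shared numbers are only names. The block changed the call of the transcription factor list (adjusted p = 0.0354) and no other list, and ended the call of 5 named genes.

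Among the lists of the study's classes, fry kept the calls of chemokine receptors, MHC class II and MHC class I and added the endocytic receptors (adjusted p = 0.00375) and the transcription factors (adjusted p = 0.00413). Quantile normalisation added the transcription factors (adjusted p = 0.0372) and, outside those classes, type I interferon genes (adjusted p = 0.0376). Without 1 array the transcription factors ranged from an adjusted p of 0.0174 to 0.149. With an estimated correlation the calls of chemokine receptors (adjusted p = 0.495), MHC class II (adjusted p = 0.240) and MHC class I (adjusted p = 0.258) were lost. That setting has 3 degrees of freedom, so a lost call does not show that the list did not shift. Of 143 named genes, 16 lost their call under an alternative other than the 2-fold test, 14 of them without 1 array, and the 2-fold test ended 46 calls. Actb alone reversed, to -0.34 with the highest-mean rule; its 2 probe sets differ. For the other changes the cause was not tested. The planned filter on dim genes was not run, since centred values hold no level, and signal over background is unknown, so a gene near background cannot be told from one with no change.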

Other observations

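The tests in this part were chosen after the results were seen. The next 6 probe sets, each shared by several genes and left out of the gene test, were picked after their values were seen and stand for no others. One shared by H2-Q6, H2-Q8 and H2-Q4, nonclassical MHC class I genes, was higher in brain DCs by 4.31 (0.52 ± 0.17 SD, n = 2, against -3.79 ± 0.30 SD, n = 3). The probe sets shared by H2-DMb1 and H2-DMb2, which encode a chain of the class II peptide editor, were higher by 4.12 and 3.57, and one shared by Isg15 and Gm9706 by 3.05. The probe set shared by Ly6c1 and Ly6c2, surface markers of classical monocytes, was at 1.13 ± 0.04 (SD, n = 2) in brain DCs and 3.05 ± 0.04 (SD, n = 3) in monocytes, a difference of -1.92. A probe set shared by adult beta globin genes was higher by 3.36, while Hba-a1, an alpha globin gene, was at 0.09 and not called. These probe sets were not tested by gene and carry no adjusted p.

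Sex-linked transcripts separated the groups although all samples are labelled female. One hypothesis is that the monocyte arrays were made from male mice: all 3 Xist probe sets were lower there without overlap, and Eif2s3y, Kdm5d and Uty were higher on their most variable probe sets, though the groups overlapped on 2 other probe sets of Kdm5d and 1 of Uty. A second is that the brain DC arrays hold RNA of both sexes, since Xist lay far above the monocyte arrays there while Eif2s3y stayed at 5.827 or more above its baseline in both. On their most variable probe sets, however, Kdm5d (0.28 and 1.47) and Uty (0.86 and 0.98) lay nearer their baselines in these arrays. The arrays behind the baseline are not known, so these values give no share of either sex. The 5 melanocyte genes had a median difference of 0.107. That argues against Y-linked RNA from the B16 tumour only if the tumour cells expressed these genes detectably, which is unknown. Pooling of animals and a wrong label are not separated by these values, and no biological explanation was tested.

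Microglial genes were higher in brain DCs. Carry-over of RNA from whole brain, in the proportions of the tissue, is argued against, but only if neuron and oligodendrocyte genes lay above background, which is unknown. In all 6 pairings of a brain DC with a monocyte array, the microglial median exceeded the neuron and oligodendrocyte median by at least 0.9875. The neuron and oligodendrocyte genes had an SD of 0.437, although Cnp among them was higher by 1.72. The pairings reuse the same arrays, and the SD as a yardstick was chosen after the values were seen. Carry-over from choroid plexus, astrocytes or endothelium stays open: Ttr (7.22), Aldoc (2.61), Clu (1.77) and Cldn5 (2.56) were higher, and the gap to the 20 genes of these lists, at least 0.9304, is smaller than their SD of 1.65. Microglia among the sorted cells may contribute: 11 of 12 measured microglia genes were higher, with a lowest microglial median of 1.378 over the pairings. Trem2, at 0.07, was not called. The gate took CD45-high cells, but how many microglia it left in was not measured. No microglia array was analysed here, so expression of these genes by brain DCs themselves stays open, and was not tested.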
